A study of Mus musculus with 6 samples.

How the data were processed

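The brains of 6 mouse embryos at embryonic day 11.5 were profiled on Affymetrix mouse expression arrays, 1 brain per array, 3 from untreated mothers and 3 from mothers made diabetic with streptozotocin, a toxin of the insulin-producing beta cells. Per the labels, the mice were Swiss albino, total RNA was labelled with biotin, and the brains from diabetic mothers were malformed ones. Groups and replicate numbers were taken from the sample titles.

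The deposited values are linear probe set intensity values, 1 column per array, in 2 value tables. The first table holds control replicates 1 and 2 and diabetic replicates 1 and 2 on the MOE430A chip, and the second holds control replicate 3 and diabetic replicate 3 on the Mouse430A_2 chip, per the file headers. The Affymetrix software GCOS is named in the submitters' processing notes, and its version, algorithm and settings are not given in the sources used here. Every deposited array had a trimmed mean of 500 after removal of 2% of the values at each end, as scaling in that software gives. The run settings deposited with each array, text other than expression values, gave a different scanner type and fluidics protocol for each table, per the file headers. They also gave 6 distinct run days for the 6 arrays, so a run day could not be used as a block. How background and probe pairs were combined stays unknown, and signals of low probe sets depend on that step.

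Each table lists 22690 probe sets, of which 64 are array controls. In the probe annotation, 20380 probe sets name 1 gene, 691 name several genes and 1555 list none, and genes were named only from probe sets with 1 gene. Of the 1-gene probe sets, 20351 matched an identifier in a RefSeq gene table, which changed 0 symbols. No genome build is named with the values, so no coordinates are given. Arrays were rescaled to a trimmed mean of exactly 500, which moved values by at most 0.0363%, and log2(signal + 32) was taken. A fold change on this scale understates the change of genes with low signal. Each of 12393 genes was represented by its probe set of highest mean log2 signal, and the 8627 genes with a mean signal of at least 100 were tested. For arrays no counting depth exists, and the number of arrays limits the precision: the median standard error of a log2 change was 0.17.

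Diabetic and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05), with the value table as a block, so that every difference was taken within a table. The fit had 3 residual degrees of freedom and a prior worth 6.48 more. The 26 gene lists, the comparison, its alternatives and the rule for named genes were fixed before the data were examined. The lists were glycolysis, hypoxia response, neuronal differentiation, neuronal migration and axon guidance, neural progenitor and Notch, dorsoventral and regional patterning, Hox genes, cell cycle, p53 targets and apoptosis, oxidative stress defence, unfolded protein response, oxidative phosphorylation, sterol synthesis, ribosomal proteins, folate and one-carbon metabolism, mouse neural tube defect genes, insulin, IGF and glucose response, immediate early and heat shock, and markers of erythroid cells, mesenchyme and meninges, endothelium, surface epithelium, neural crest and glia, muscle, macrophages, and eye and lens. Of 690 listed symbols found on the arrays, 598 were among the genes tested. Lists with at least 5 tested genes were compared with all other genes by camera with a preset inter-gene correlation of 0.01, with camera using an estimated correlation beside it. Beside these, fry tested whether the genes of a list move to 1 side on balance, which compares a list with no other genes. Named genes were the 12 higher and 12 lower genes with the largest change among those past the threshold whose diabetic arrays all lay on 1 side of the control arrays within each table, filled up with the genes of smallest unadjusted p that met the same condition, and up to 4 tested members of smallest p from each list. Genes of embryo sex were left out of the named genes. Of the named genes, 51 had several tested probe sets, and for 12 of these the probe sets differed in sign: Atp5a1, Csf1r, Dnajc3, Dnmt3a, Mtfr1, Notch3, Sdhc, Sox10, Sox17, Sparc, Tfap2a and Trp53inp1. The other probe sets of opposite sign had log2 changes of 0.17 for Notch3, 0.15 for Mtfr1, 0.039 for Sparc, and 0.087 and 0.16 for Dnmt3a, against -0.29 for Sdhc, whose 2 probe sets had mean signals of 1959 and 1804. Counting those, 29 of the 51 had a probe set with less than 50% of the change of the one used, and of the genes given in the text these others were 0.35 and 0.29 for Ak4, -0.17 for Ebf2, -0.20 for Elavl4, -0.23, -0.14 and -0.031 for Enah, -0.33 and -0.21 for Igf1, 0.062 for Mvd, -0.00044 for Pdgfra, -0.018 for Phf20l1, 0.20 for Rpl22 and -0.23 for Xbp1.

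On simulated data for this comparison, over 8627 genes with 3 arrays in each group, limma called 71 of 100 genes changed by 1 on the log2 scale, 100 of 100 changed by 2, and 5 of 8427 unchanged genes. Camera called 5 of 5 simulated lists raised by 0.3 and 0 of 21 unchanged lists. The simulated genes were independent of each other, so this says nothing about lists whose genes vary together. Array quality values were compared by exact permutation tests, whose smallest two-sided p with 3 against 3 arrays is 0.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used besides R.

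The replicate numbers of the labels were checked for pairing before the calls of the fits were compared. Deviations from the group means correlated across genes at 0.45, 0.43 and 0.74 for the same-numbered arrays, above the limit of 0.1 set for a pairing. Control replicate 2 and diabetic replicate 1 correlated at 0.57, and within the first table the difference between replicates 1 and 2 correlated at -0.0091 between the groups. The pairing therefore comes from the table that same-numbered arrays share, which the block already holds. Alternatives were a block on the replicate number, pseudocounts of 1 and 100, no filter on low signal or a limit of 200, quantile normalization within each table, values as deposited, the first table alone, array weights, another variance prior, the mean of a gene's probe sets, all probe sets, and leaving out each array.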

Results

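The data set holds 6 arrays of mouse embryonic brain at E11.5, when the neural tube has closed and the first neurons are forming: 3 from embryos of untreated mothers and 3 malformed brains from embryos of diabetic mothers. Because the brains of the diabetic group were also malformed ones, maternal diabetes and malformation cannot be told apart in any comparison. The design sets separate brains on separate arrays, and it does not say whether brains shared a litter. Median deposited signals were 221, 222 and 165 for control replicates 1 to 3 and 227, 210 and 173 for diabetic replicates 1 to 3, with the lower values in the second table. Across genes, arrays of the same table correlated at 0.958 to 0.982 and arrays of different tables at 0.921 to 0.950, so all comparisons were made within tables.

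The first comparison asked which genes differ in the brain between embryos of diabetic and untreated mothers. The lowest value among the named genes belonged to Ttr, transthyretin, a carrier of thyroid hormone and retinol made in the choroid plexus, with a log2 change of -2.97 ± 0.54 (SE, n = 3 per group). Its signals were 1149, 1114 and 3003 on control replicates 1 to 3 and 121, 11.4 and 1251 on diabetic replicates 1 to 3. Dkk2, a secreted modulator of Wnt signalling, had -1.08 ± 0.17, and Aldoa, the glycolytic aldolase, stood at the other side with 0.93 ± 0.20, its mean signal being 3784 ± 1728 (SD, n = 3) in controls and 6992 ± 2859 (SD, n = 3) in the diabetic group. None of these genes passed the adjustment: limma called 0 of 8627 genes, with a smallest adjusted p of 0.527.

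Among the 12 genes named on the higher side, Oas1a, an interferon-induced enzyme, had a log2 change of 1.52 ± 0.34 (SE, n = 3 per group), and Cd248, a marker of pericytes and mesenchymal cells, had 1.02 ± 0.24. Oas1a had 2.08 in the first table and 0.40 in the second, and Cd248 had 1.37 and 0.32. Serpinf2, which encodes the plasmin inhibitor alpha-2-antiplasmin, had 0.98 ± 0.15, Col11a2, a fibrillar collagen chain, 0.85 ± 0.17, and Itga5, a subunit of the fibronectin receptor, 0.74 ± 0.16. Serpinf2 signals were 86.6, 92.8 and 7.56 on control replicates 1 to 3 and 37.2 on diabetic replicate 3, where a change depends on the pseudocount. Fgf17, a growth factor of the midbrain and hindbrain region, had 0.70 ± 0.15. The others were Aldoa, Diras1, Ctla2a, Lrrc18, Ambra1, an autophagy regulator, and Gm5802, with changes between 0.69 and 1.10. On the lower side, Cwc22, a splicing factor, had -1.10 ± 0.24, Nrk, a protein kinase, -1.07 ± 0.25, and Dlx1as, the transcript antisense to the forebrain gene Dlx1, -0.95 ± 0.21. Stxbp4 had -0.86 ± 0.17 and Far1, an enzyme of ether lipid synthesis, -0.77 ± 0.17, with -0.36 to -0.12 for its 4 other probe sets, while Ankrd44, Zfp617, Csgalnact2, Phf20l1 and Mtfr1 lay between -0.88 and -0.72. All 24 were named for the smallest unadjusted p among genes without overlap, and 0 of them passed the adjustment in limma.

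**Figure D1:**
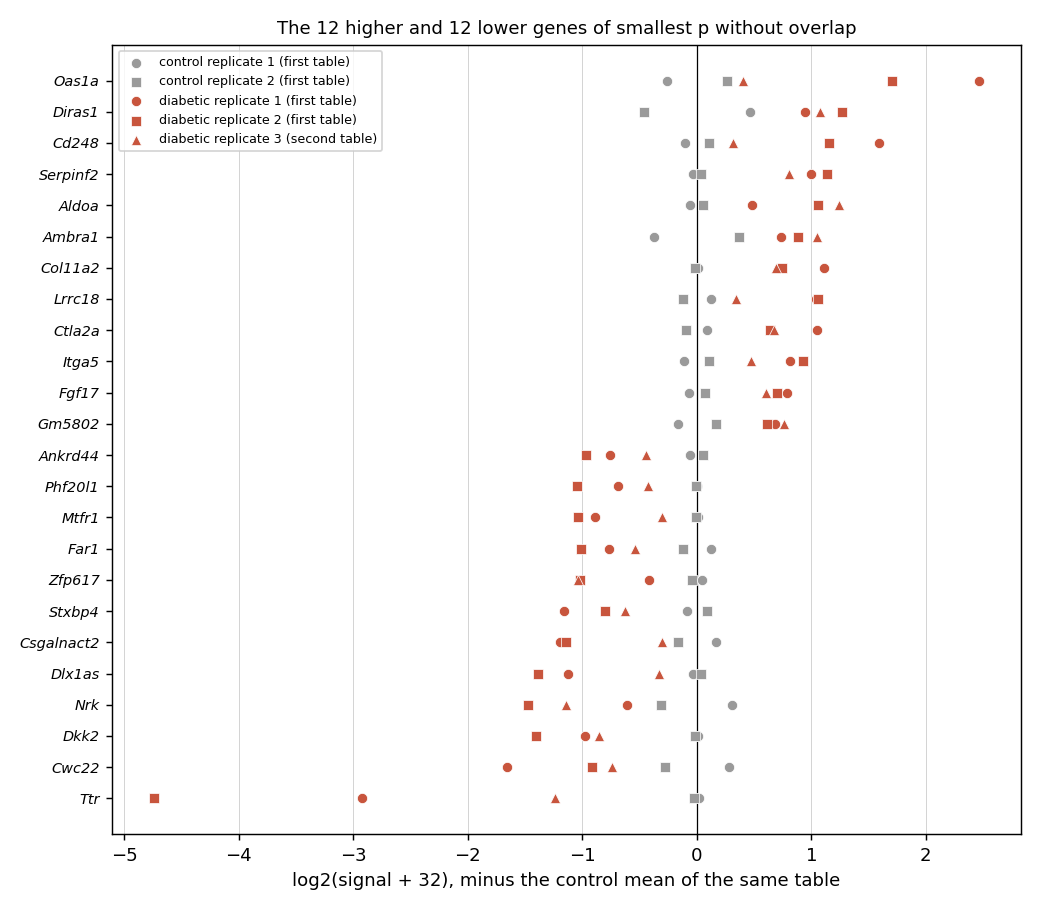
Log2(signal + 32) of the 12 higher and 12 lower named genes on each array, minus the mean of the control arrays of the same table, with control replicate 3 at 0 by construction and not drawn. Diabetic arrays (red) lie on 1 side of the control arrays (grey) for every gene, since the genes were named for that, and Ttr reaches the lowest values, with a log2 change of -2.97 in the fit.

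At an unadjusted p under 0.05, limma counted 659 genes, 322 higher and 337 lower in the diabetic group, where chance alone gives 431. The diabetic arrays lay beyond the control arrays of their table for 977 genes on the higher and 913 on the lower side, 21.9% of the genes tested against 16.7% by chance. Log2 changes in the first table and in the second table correlated across genes at 0.039 and shared their sign for 51.5% of genes, genes being no independent replicates. Without control replicate 1 the count at an unadjusted p under 0.05 was 414.

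The second comparison asked whether fixed gene lists shifted as groups. Transcripts of glycolysis, the pathway from glucose to pyruvate and lactate, were higher in the diabetic group: 19 of 20 measured members lay above 0, with a median log2 change of 0.59. Slc16a3, the lactate exporter, had 1.78 ± 0.43 (SE, n = 3 per group), Pfkl, the liver-type phosphofructokinase, 0.78 ± 0.18, and Ldha, lactate dehydrogenase A, 0.70 ± 0.19, while Ldhb was the exception with -0.14 ± 0.16. Adjusted over all genes tested, 0 members passed in limma, and adjusted over the list alone, 5 higher members passed, namely Aldoa, Pfkl, Slc16a3, Ldha and Tpi1, the last of these named after its values were seen. Camera gave the list an adjusted p of 5.4e-10, and an adjusted p = 0.771 with an estimated correlation. List medians on diabetic replicates 1 to 3 were 0.19, 1.04 and 0.37 above the control mean of their table, and without diabetic replicate 2, which stood apart, the median was 0.29 with 17 of 20 members higher and a camera adjusted p of 1.97e-05. Without that array Slc16a3 had a log2 change of 1.16, and Ldhb ranged from -0.20 to -0.078 as single arrays were left out.

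Transcripts of the hypoxia response were also higher as a list, with 16 of 18 members above 0 and a median of 0.44. The list was made of targets of the oxygen-sensing transcription factors and of the factors Hif1a and Epas1 themselves. Bnip3, a mitophagy receptor, had a log2 change of 1.07 ± 0.48 (SE, n = 3 per group), Ak4, a mitochondrial adenylate kinase, 0.76 ± 0.26, and Vegfa, the endothelial growth factor, 0.70 ± 0.30, whereas Lox, a collagen cross-linking enzyme, had -0.49 ± 0.21 and Hif1a, named after its values were seen, -0.35 ± 0.20. As single arrays were left out, log2 changes ranged from 0.34 to 1.71 for Bnip3, -0.81 to -0.35 for Lox and -0.58 to -0.15 for Hif1a, and without diabetic replicate 2 Bnip3, Ak4 and Vegfa had 0.34, 0.40 and 0.31. Lox had -0.81 in the first table and 0.15 in the second. Adjusted over all genes tested and adjusted over the list alone, 0 members passed in limma. Camera gave an adjusted p of 0.0020, and an adjusted p = 0.819 with an estimated correlation. The list medians were -0.074, 1.27 and 0.25 on diabetic replicates 1 to 3, and without diabetic replicate 2 the median was 0.069, with 10 of 18 members higher and a camera adjusted p of 0.809. With array weights the median was 0.23 and the camera adjusted p was 0.276.

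**Figure D2:**
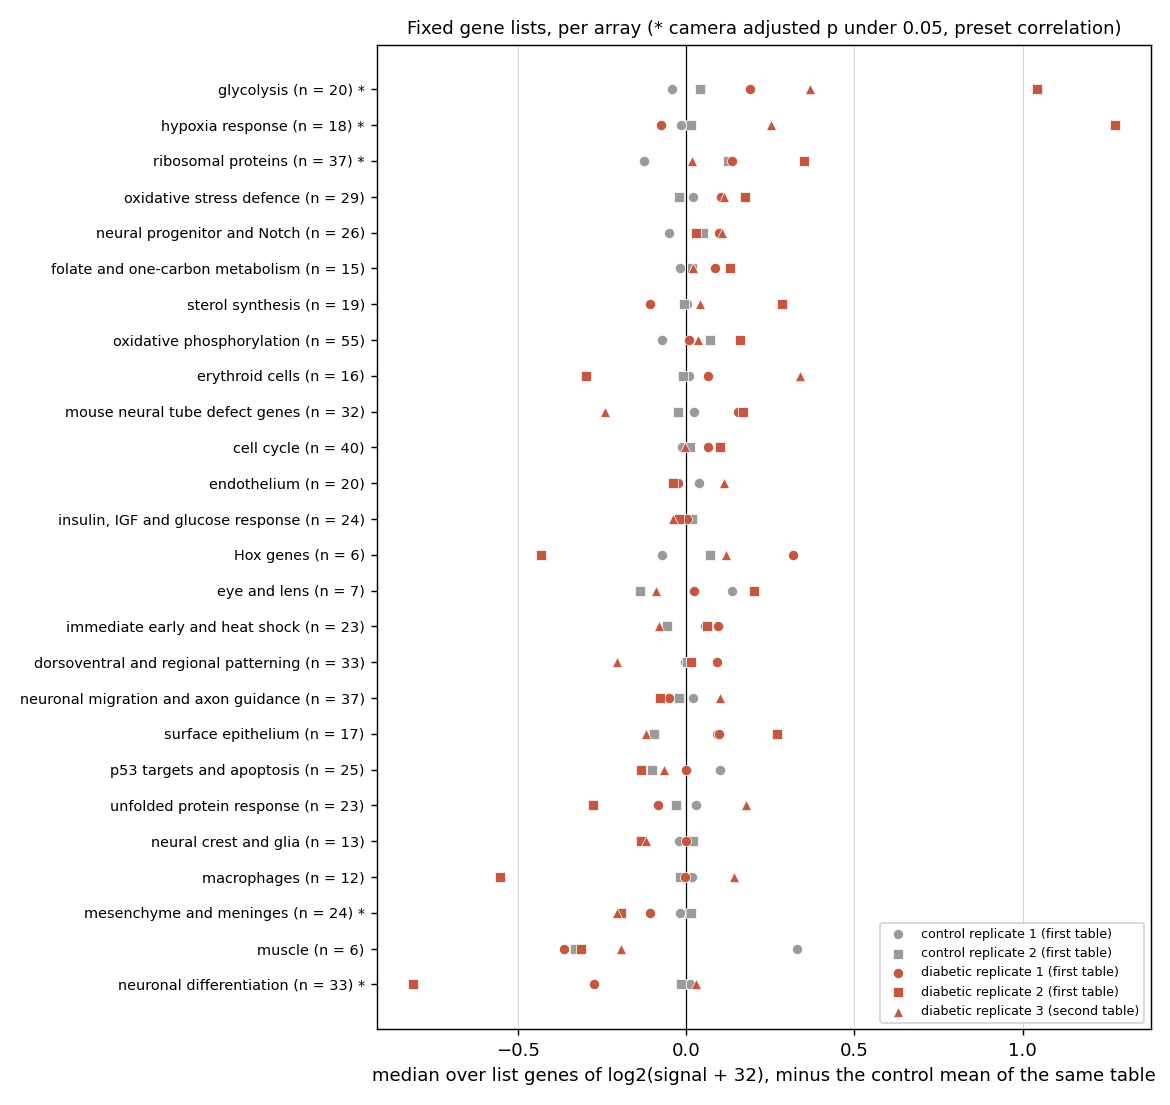
Median over the tested genes of each fixed list of log2(signal + 32), minus the control mean of the same table, for each array, with control replicate 3 at 0 by construction and not drawn. Diabetic replicate 2 (red squares) has the highest medians for glycolysis (1.04) and hypoxia response (1.27) and the lowest for neuronal differentiation (-0.81).

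Transcripts of neuronal differentiation were lower in the diabetic group as a list, with 31 of 33 members below 0 and a median of -0.35. Insm1, a transcription factor of newborn neurons, had a log2 change of -0.82 ± 0.24 (SE, n = 3 per group), Ebf2, another early neuronal transcription factor, -0.78 ± 0.30, Ina, the neurofilament alpha-internexin, -0.76 ± 0.25, and Elavl4, a neuronal RNA-binding protein, -0.60 ± 0.16. The members above 0, both named after their values were seen, were Elavl3 with 0.13 ± 0.18 and Syt1 with 0.098 ± 0.27. Adjusted over all genes tested and adjusted over the list alone, 0 members passed in limma. Camera gave an adjusted p of 1.48e-07, and an adjusted p = 0.819 with an estimated correlation. The median was -0.52 in the first table and 0.030 in the second, with -0.27 on diabetic replicate 1 and -0.81 on diabetic replicate 2, and without diabetic replicate 2 it was -0.033, with 18 of 33 members lower and a camera adjusted p of 0.122. Without that array Insm1 and Ina had log2 changes of -0.52 and -0.43. As single arrays were left out, Ebf2 ranged from -1.18 to -0.38, Elavl3 from -0.019 to 0.29 and Syt1 from -0.39 to 0.29.

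**Figure D3:**
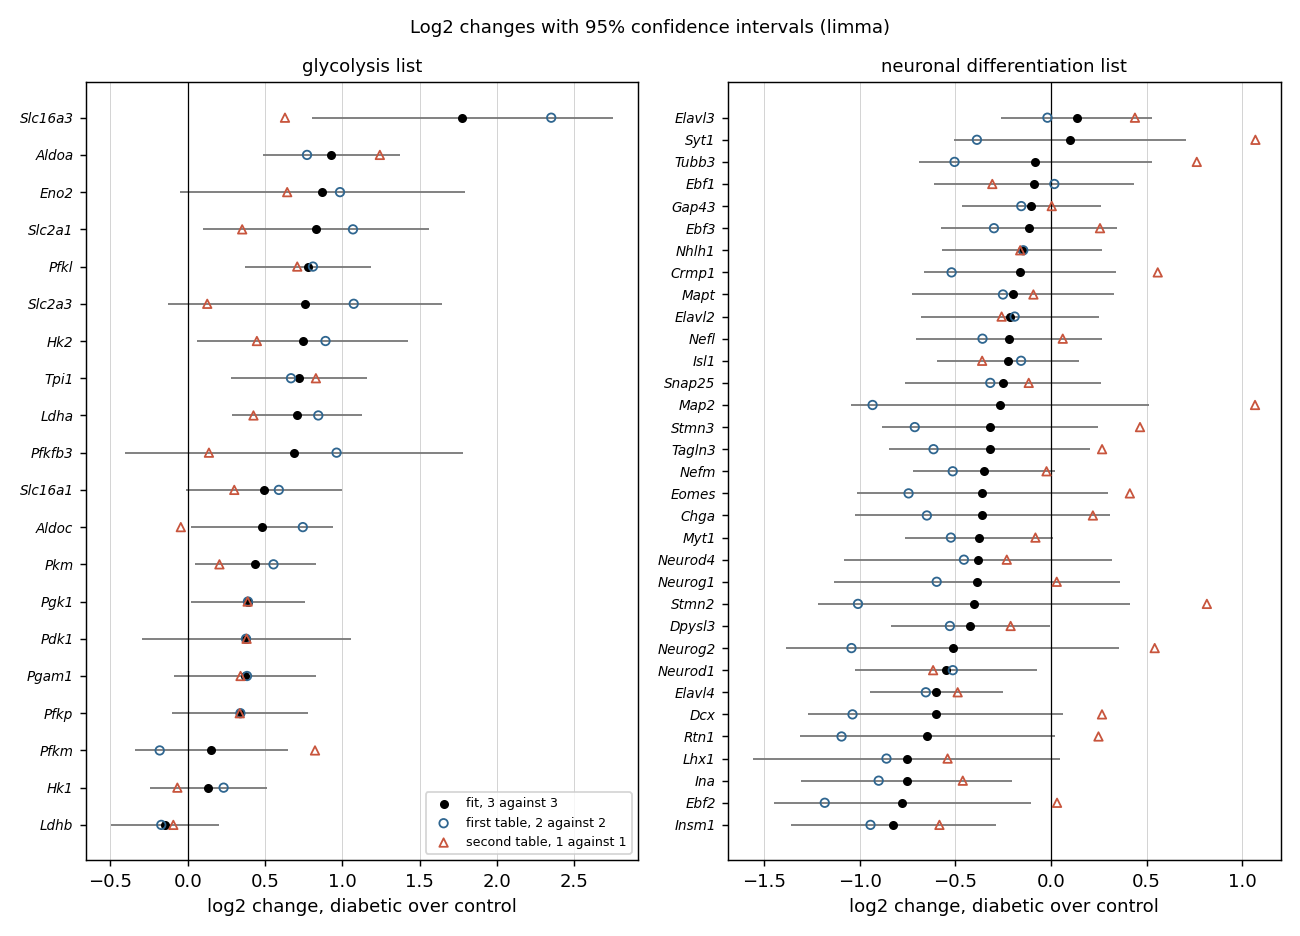
Log2 change, diabetic over control, of each tested gene of the glycolysis list (left, 20 genes) and the neuronal differentiation list (right, 33 genes), with 95% confidence intervals from limma and the changes in the first table (blue circles) and the second table (red triangles). In the glycolysis list 19 genes lie above 0, and in the neuronal list the second table's values scatter around a median of 0.030 while those of the first have a median of -0.52.

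Ribosomal protein transcripts were higher as a list by a smaller amount, a median of 0.19, with 34 of 37 members above 0. Rpl22 had a log2 change of 0.50 ± 0.27 (SE, n = 3 per group), Rps27 0.35 ± 0.16 and Rpl12 0.34 ± 0.18, and Rps25 had -0.31 ± 0.18. Adjusted over all genes tested and adjusted over the list alone, 0 members passed in limma. Camera gave an adjusted p of 7.68e-04, and an adjusted p = 0.819 with an estimated correlation. List medians on diabetic replicates 1 to 3 were 0.14, 0.35 and 0.019 above the control mean of their table, with 34, 35 and 22 of 37 members above it. As single arrays were left out, log2 changes ranged from 0.19 to 0.78 for Rpl22, 0.17 to 0.48 for Rpl12 and -0.42 to -0.076 for Rps25, which had -0.076 in the first table and -0.78 in the second. The call ended with quantile normalization (median 0.017, camera adjusted p 0.809), without control replicate 1, the array with the highest 18S ribosomal RNA signal (0.073, 0.329), and without diabetic replicate 2 (0.11, 0.251).

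Markers of mesenchyme and meninges, the connective tissue around the brain, were lower as a list, with 19 of 24 members below 0 and a median of -0.21. Foxd1, a transcription factor, had a log2 change of -0.63 ± 0.21 (SE, n = 3 per group), Postn, periostin, -0.56 ± 0.19, Pdgfra, a growth factor receptor, -0.42 ± 0.20, and Sparc, a matrix protein, -0.41 ± 0.19. Pdgfra had -0.64 in the first table and 0.014 in the second, and as single arrays were left out it ranged from -0.64 to -0.22 and Sparc from -0.56 to -0.23. Adjusted over all genes tested and adjusted over the list alone, 0 members passed in limma. Camera gave an adjusted p of 0.0025, and an adjusted p = 0.771 with an estimated correlation. The medians were -0.11, -0.19 and -0.20 on diabetic replicates 1 to 3, with 17 of 24 members below the control mean on each, and the median without diabetic replicate 2 was -0.17 with a camera adjusted p of 0.0038.

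Markers of the other cell types that a dissected head could hold did not pass in camera. Muscle markers had a median of -0.31 over 6 genes, with Myod1, the myogenic regulator, at -0.50 ± 0.17 (SE, n = 3 per group), and a camera adjusted p of 0.0828, which became 0.0434 with the replicate number as a block, in the same direction. With the table as the block, camera gave muscle markers an adjusted p = 0.819 with an estimated correlation. Macrophage markers had a median of -0.16 over 12 genes, with Mrc1, the mannose receptor, at -0.65 ± 0.19, and neural crest and glia markers -0.15 over 13 genes, with Fabp7, a fatty acid binding protein of radial glia, at -0.62 ± 0.22 (-0.37 without diabetic replicate 2). Without that array the macrophage median was 0.055. The erythroid median was 0.073 over 16 genes, with Alas2, the erythroid haem synthesis enzyme, at 0.38 ± 0.22 (0.15 in the first table and 0.84 in the second). That of surface epithelium was -0.026 over 17 genes, 8 higher and 9 lower. Cldn3, a tight junction protein, had 0.64 ± 0.19, against -0.60 ± 0.17 for Perp and -0.73 ± 0.24 for Krt5. Krt5 had -1.13 in the first table and 0.058 in the second. Endothelial markers had a median of 0.028 and a mean of -0.0097 over 20 genes. Adjusted over the list alone, 1 endothelial gene passed on each side in limma, against 0 over all genes: Plvap, a protein of fenestrated vessels, with 0.57 ± 0.15, and Fli1, an endothelial transcription factor, with -0.74 ± 0.20. Eye and lens markers had a median of -0.0047 and a mean of 0.010 over 7 genes, the direction of camera being that of the mean, and Crybb3, a lens crystallin, had 0.50 ± 0.18.

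Among the lists of brain development, none of those left passed in camera. Progenitor and Notch genes had a median of 0.14 over 26 genes, with Sox1, a transcription factor of the neural plate, at 0.63 ± 0.16 (SE, n = 3 per group) and Notch3 at -0.39 ± 0.16; in the first table alone the list's median was -0.038 and Notch3 had -0.25. Regional patterning genes had a median of -0.0071 and a mean of 0.0084 over 33 genes, with Shh, the ventral signal, at 0.53 ± 0.19, Dlx1 at -0.58 ± 0.19 and Msx1, a dorsal midline gene, at -0.50 ± 0.19. Adjusted over the list alone, 1 patterning gene passed in limma, Fgf17, against 0 over all genes. Migration and axon guidance genes had a median of -0.010 over 37 genes, with Sema3f, a repellent guidance cue, at 0.56 ± 0.19 and Robo1, a Slit receptor, at -0.55 ± 0.20. Cell cycle genes had a median of 0.049 over 40 genes (0.086 in the first table and -0.0044 in the second), with E2f1 at 0.42 ± 0.16. Mouse neural tube defect genes had 0.061 over 32 genes, with Enah, an actin regulator, at -0.54 ± 0.24. In the first table alone camera called the neural tube defect genes higher (median 0.17, adjusted p 0.0218), while their median in the second table was -0.24. Over both tables camera gave this list an adjusted p of 0.764, and an adjusted p = 0.968 with an estimated correlation. The 6 Hox genes tested had a median of 0.00078 and a mean of -0.061, and Hoxa2 had -0.29 ± 0.21. As single arrays were left out, log2 changes ranged from -0.82 to -0.24 for Enah, -0.64 to -0.33 for Msx1 and -0.52 to -0.12 for Hoxa2.

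Among the stress and fuel lists, oxidative stress defence had a median of 0.16 over 29 genes, with the metallothionein gene Mt1 at 0.55 ± 0.27 (SE, n = 3 per group), and oxidative phosphorylation 0.075 over 55 genes, with Sdhc, a subunit of succinate dehydrogenase, at 0.41 ± 0.18, against -0.29 for its other probe set and 0.28 without control replicate 1. Sterol synthesis had a median of 0.090 over 19 genes, with Mvd, mevalonate decarboxylase, at 0.51 ± 0.16. The unfolded protein response had -0.12 over 23 genes, with Trib3, a pseudokinase induced by stress, at 0.87 ± 0.22 and Xbp1 at -0.62 ± 0.31. P53 targets and apoptosis genes had a median of -0.084 over 25 genes, with Perp at -0.60 ± 0.17, and folate and one-carbon genes 0.090 over 15 genes, with the DNA methyltransferase Dnmt3a at -0.49 ± 0.20. The folate median was 0.17 in the first table and 0.021 in the second. Insulin, IGF and glucose response genes had a median of 0.028 over 24 genes, with Txnip, a gene induced by glucose, at 0.64 ± 0.22 and Igf1 at -0.80 ± 0.25. Immediate early and heat shock genes had a median of -0.0062 and a mean of 0.14 over 23 genes. The heat shock gene Hspa1b had 1.39 ± 0.68, carried by diabetic replicate 2, with signals of 209, 2202 and 255 on diabetic replicates 1 to 3. Its change ran from 0.34, without diabetic replicate 2, to 2.18 as single arrays were left out. The same ranges were 0.20 to 0.90 for Mt1 and -0.90 to -0.26 for Xbp1, and without diabetic replicate 2 Dnmt3a, Txnip and Igf1 had -0.28, 0.37 and -0.49. Over the lists that did not pass, camera adjusted p ran from 0.0828 to 0.955, and adjusted over the list alone, 0 genes passed in limma outside the glycolysis, patterning and endothelial lists.

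Measures of RNA quality overlapped between the groups. The 3′ over 5′ signal ratio of the Gapdh control probe sets was 0.773 ± 0.063 (SD, n = 3) in the diabetic and 0.782 ± 0.050 (SD, n = 3) in the control group, with an exact permutation p of 0.7, and that of beta-actin gave an exact permutation p of 1.0. The smallest p this design allows is 0.1. Control replicate 1 had an 18S ribosomal RNA signal of 7894, against 101 to 265 on the other arrays. Embryo sex, which the labels do not give, was spread alike over the groups: replicate 1 of each had the highest Xist signal of its group (6677 in control, 1816 in diabetic) and Eif2s3y signals of 16.8 and 13.4, while on the other arrays the Y-linked Eif2s3y ranged from 267 to 355.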

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

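The control probe sets of the array, which enter no gene test, were looked through after the main results had been seen. The probe sets of the poly-A spike-in transcripts (dap, lys, phe and thr), bacterial RNAs added in known amounts before labelling, were picked for their ratios in the second table. The 12 of the newer design had a median ratio of 1.85 for diabetic replicate 3 over control replicate 3, with a range of 1.23 to 2.26, and the 12 of the older design for the same transcripts had a median of 1.94 and a range of 1.27 to 2.19. On every diabetic array 3 of the 12 newer and 6 of the 12 older ones were higher than on the control arrays of the table. In the first table the newer ones had a median ratio of 1.25 and the older ones of 1.49, at median signals of 13.8 and 16.2, near the floor. The 3 probe sets of trpn, in the older design alone, had a median second-table ratio of 0.551 at a median signal of 1.98. The probe sets of the hybridization spike-ins, added after labelling, had a median ratio of 0.728 on the second-table arrays.

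A search for control probe sets other than spike-ins that were higher on every diabetic array than on the control arrays of its table, with a mean signal of at least 100 and a fold of at least 1.5, gave a pair. The 3′ control probe set of the transferrin receptor was 1.69-fold higher in the diabetic group, 1.35-fold in the first table and 2.62-fold in the second, while the gene's own probe set, Tfrc, had a log2 change of 0.38. The other control probe sets of that transcript had first-table and second-table folds of 1.10 and 2.99 (5′) and 0.793 and 3.05 (M), and neither was higher on every diabetic array. A control probe set of pyruvate carboxylase, named MA on the array, was 1.59-fold higher, 1.27-fold in the first table and 2.48-fold in the second. Its siblings had 1.01 and 1.18 (3′), 1.13 and 1.08 (5′), and 0.933 and 2.37 (MB), and only the 5′ one was higher on every diabetic array. These ratios were not tested.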

How the results depend on the processing

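The number of genes called by limma was 0 in every alternative run, with smallest adjusted p between 0.055 and 0.952, and the replicate number as a block changed no call other than that of the muscle markers. The number of lists called by camera was 5, and it was 0 with an estimated correlation and 2 to 8 when single arrays were left out (0 to 0 genes), the 2 being glycolysis and mesenchyme without diabetic replicate 2 and the 8 without diabetic replicate 1. Estimates were 0.55 for glycolysis, 0.62 for neuronal differentiation, 0.61 for hypoxia and 0.70 for ribosomal proteins. These lie above the preset value, so p-values with the preset can be too small there. For mesenchyme the estimate was -0.032 and the unadjusted p 0.030. Why calls were otherwise lost, or others shifted, was not tested. Over the 18 settings with camera, adjusted p ran from 1.05e-16 to 0.771 for glycolysis (17 past the threshold), 2.83e-11 to 0.819 for neuronal differentiation (16), 1.03e-05 to 0.819 for ribosomal proteins (14), 2.83e-11 to 0.819 for hypoxia (15) and 6.96e-04 to 0.771 for mesenchyme (17). Fry, which compares a list with no other genes and so asks another question, called 0 lists, its adjusted p being 0.448 for glycolysis, 0.0819 for mesenchyme and 0.728 for each of the other 3. Calls gained with camera were those of macrophages with no filter (median -0.17, adjusted p 0.0080), in the first table alone (-0.23, 0.0168) and without diabetic replicate 1 (-0.31, 0.0198), of muscle with no filter (-0.26, 0.0018), without control replicate 2 (-0.49, 0.0021) and with the replicate block (-0.31, 0.0434), of neural tube defect genes in the first table alone (0.17, 0.0218), and of oxidative phosphorylation (0.10, 0.0476) and sterol synthesis (0.19, 0.0059) without diabetic replicate 1. Without diabetic replicate 2, 14 of 124 named genes kept less than 50% of their log2 change or turned, and 62 of 124 moved by over 1.5 times or turned when some single array was left out. With the replicate block the gene count was 0 and the list count 6. Leaving out control replicate 3 or diabetic replicate 3 gives the same fit as the first table alone, because the array left in the second table is taken up by the block. The values as deposited differ too little from the rescaled ones to test anything. Genes at an unadjusted p under 0.05 ranged from 414 to 883 over the gene-level alternatives, and were 1081 over all probe sets, which are more numerous. The 5 lists called kept their direction in each of the 19 settings, while the camera direction of 12 lists that were not called turned in some setting, as did the sign of 10 of 124 named genes. For these the list medians, or log2 changes of genes, were as follows, the direction of camera not always being that of the median. With the replicate block, immediate early genes had -0.0062 and endothelium 0.028. With a pseudocount of 100 patterning genes had -0.0093, with no filter patterning had -0.020 and surface epithelium 0.040, and with a limit of 200 patterning had -0.056, immediate early genes 0.0051 and surface epithelium 0.050. With quantile normalization eye and lens had -0.036 and Hbb-bh1 -0.013. In the first table alone immediate early genes had 0.059, erythroid cells -0.062, endothelium -0.032, surface epithelium 0.13, Hoxa9 -0.21 and Epb42 -0.0054. With array weights Hox genes had 0.053 and surface epithelium 0.053. With the mean of all probe sets p53 targets had 0.055, surface epithelium 0.050, Hoxc6 -0.055, Atp5a1 -0.017, Sox17 0.078 and Tfap2a 0.030. Leaving out single arrays gave ranges of -0.069 to 0.059 for immediate early genes, -0.032 to 0.085 for endothelium, -0.064 to 0.079 for patterning, -0.090 to 0.13 for surface epithelium, -0.12 to 0.16 for eye and lens, -0.062 to 0.13 for erythroid cells, -0.16 to 0.19 for Hox genes, -0.045 to 0.030 for migration and axon guidance, 0.014 to 0.17 for neural tube defect genes, -0.23 to 0.038 for the unfolded protein response and -0.044 to 0.19 for sterol synthesis. The ranges for genes were -0.21 to 0.64 for Hoxa9, -0.0054 to 0.41 for Epb42, -0.024 to 0.27 for Prox1, -1.04 to 0.32 for Hoxb3 and -0.45 to 0.14 for Dct. Medians also turned where camera kept its direction: those of progenitor genes in the first table alone (-0.038), of macrophages without diabetic replicate 2 (0.055), of p53 targets (0.036) and the unfolded protein response (0.038) without control replicate 1, of sterol synthesis (-0.0013) and insulin response genes (-0.0022) with array weights, and in several settings those of lists with medians near 0, namely Hox genes, eye and lens, migration and axon guidance, immediate early and patterning genes. Genes of mean signal near 100 lie close to the background of these arrays, and changes there are understated by the pseudocount.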

Other observations

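The tests in this part were chosen after the results they bear on had been seen, except the comparison of the glycolysis, hypoxia and neuronal lists with signal-matched random lists.

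Several genes with large changes belong to groups for which no list had been fixed, and lists for these groups were assembled only after such genes had been seen. Genes of ventral forebrain GABAergic neurons were lower: 14 of 16 lay below 0, with a median log2 change of -0.20 and a camera p of 2.2e-05 (0.060 with an estimated correlation). Genes of the amino acid response, which include amino acid transporters, tRNA synthetases and enzymes of serine synthesis, were higher: 18 of 20 lay above 0, with a median of 0.18 and a camera p of 9.19e-05 (0.024 with an estimated correlation). Interferon response genes had a median of 0.17, with 8 of 12 above 0 and a camera p of 0.0931 (0.175 with an estimated correlation). These values are circular, since the members seen beforehand had prompted the lists. One hypothesis is that each group shifts as a whole, and it was tested on the members not seen before. Over the 5 left of the GABAergic list the median was -0.047 and the camera adjusted p over the 3 lists was 0.627, over the 13 left of the amino acid list 0.094 and 0.187, and over the 9 left of the interferon list 0.16 and 0.878. No shift of the groups as wholes was detected outside the genes that prompted them, and few members were left to show one. The members left out had been seen for large changes or small p. Those left therefore lean to small changes, so the test cannot decide against a shift.

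The glycolysis and hypoxia lists were higher in the diabetic group. Of 10000 random lists matched in size and signal level, 0 had a median as high as glycolysis and 0 as high as hypoxia. The same held for ribosomal proteins, whose call ended with quantile normalization, so random lists alone decide little. Glycolysis and hypoxia stayed called with quantile normalization, and both results together argue against signal-dependent scaling. RNA degradation in diabetic replicate 2 was judged by the Gapdh 3′ over 5′ ratio of that array, 0.802. It lay below the highest of the other first-table arrays, 0.815, so the ratio gives no sign of degradation. The Gapdh control signals on that array, 14295 (3′) and 17826 (5′), lie near its highest value, 22693. A ratio of signals so near the top may hardly respond, so it cannot exclude degradation. Diabetic replicate 2 alone may account for the hypoxia result, since the camera adjusted p without it was 0.809. The glycolysis median without that array was 0.29, against 0.59 with all arrays, and diabetic replicates 1 and 3 had 0.19 and 0.37. Its camera adjusted p without that array was 1.97e-05 with the preset correlation, which cannot decide whether the rest is a group difference. The list's estimated correlation was 0.55, and camera with the preset also called glycolysis in splits that mix diabetic and control arrays. A response to the diabetic mother, to malformation, or to the handling of the tissue stays open as untested, and the lists' calls are lost with an estimated correlation.

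The neuronal differentiation list was lower in the diabetic group, a call that is lost with an estimated correlation. Of 10000 signal-matched random lists, 0 had a median as low, and the list stayed called with quantile normalization. Both results together argue against signal-dependent scaling. Diabetic replicate 2 alone may account for it, because without that array the camera adjusted p was 0.122 and the median -0.033, and the second table had a median of 0.030. Dilution of neurons by other cell types cannot be told apart. Mesenchyme markers had a median of -0.21, which bears only on dilution by mesenchyme, and their call is lost with an estimated correlation. No list of another cell type was called higher, but cell types without a list were not looked at. An earlier developmental stage cannot be told apart either, the progenitor list having a median of 0.14, a camera adjusted p of 0.532 and a median of -0.038 in the first table alone. A delay or malformation specific to the brain on that array stays open, as an untested biological difference.

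Ttr was the lowest named gene. A fault of 1 probe set is argued against by the other Ttr probe sets, whose log2 changes were -2.73 and -2.72. Liver or yolk sac RNA in the control arrays is argued against by their abundant transcripts: the highest control mean among Afp, Alb, Apoa1 and Apoa2 was 42.1, against 1755.5 for Ttr, a test put in place of an earlier version that rested on Rbp4 alone (log2 change 0.00082). A smaller roof plate and choroid plexus domain could also lower Ttr, and the list for it without Ttr had a median of -0.070 over 13 genes with a camera p of 0.194, which leaves it open. In the first table the signal of Ttr was 121 and 11.4 on the diabetic and 1149 and 1114 on the control arrays, and a difference in dissection or stage of single brains stays open too.

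With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 0 genes with limma, with 659 at an unadjusted p under 0.05, and the highest other split called 32; that 10 of 10 splits called as many or more follows from the 0 and says nothing. Counting genes at an unadjusted p under 0.05, 3 of 10 splits had 659 or more, the highest other being 890, and for lists called by camera 8 of 10 splits had 5 or more, the highest other being 11. These counts mix fits of unlike form: in 4 splits both second-table arrays lie on 1 side, so that the block takes them up and 1 array of the first table is set against 3. Among the 6 splits that part the second table as the real one does, the real one had the highest count of genes at an unadjusted p under 0.05, 659 against 228 to 604 in the others, and the lowest of lists, 5 against 5 to 9, with 0 genes called in each; 6 splits are too few as well. The 32 genes and 11 lists came with diabetic replicate 2 as the single array, against 2 genes and 5 lists with control replicate 1, 0 and 3 with diabetic replicate 1 and 0 and 4 with control replicate 2. Diabetic replicate 2 thus lies furthest from the other first-table arrays by these counts, a structure of the samples that rests on 1 array. Among the splits that part all 3 same-numbered pairs, the real one had 5 lists and the others had 7, 9 and 5, with 604, 331 and 308 genes at an unadjusted p under 0.05. By name, glycolysis, hypoxia, neuronal and ribosomal lists were also called in other splits that part the second table, and mesenchyme in the real split alone. Calls of those lists are thus not particular to diabetic against control arrays. With control replicates 1 and 2 beside diabetic replicate 3 the neuronal median was -0.39, against -0.35 in the real split. The glycolysis median was 0.59 in the real split and -0.45 to 0.42 in the others that part the second table. Control replicate 1 was always on the reference side, so the sign in those other splits is arbitrary and only the size counts. With diabetic replicate 2 as the single array the median was 0.90.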
